A study of Mus musculus with 2 samples.

How the data were processed

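ChIP-seq was done on MIN6-4N mouse insulinoma cells that overexpressed HLXB9 from a transfected plasmid. Per the labels' protocols, chromatin was prepared 48 hours after transfection, immunoprecipitated with a commercial ChIP kit, and made into Illumina libraries. There was 1 library from the immunoprecipitation with the antibody against phosphorylated HB9 and 1 input library without antibody. Reads of 36 bp were sequenced, per the series' design text.

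The only processed file is a list of peaks. Peaks were called by the authors with MACS (version written as 1.42) on the mouse build mm9, per the submitters' processing notes. The aligner, read filters, tag numbers and false discovery rates are not given in the sources used here. Of the caller settings, the name of the list appears to hold the p-value limit, which the lowest score also shows, and another number whose meaning is not stated. Each peak has a chromosome, a start, an end, a running number and a score. The score was deposited by the authors and has no header. It was read here as 10 times the negative log10 of the p-value of the ChIP tags against the background, the scale of this caller's 1.4 series. Whether that background was local, set over the whole genome or both is not given in the sources used here. The lowest value, 30, and the highest, 3100, bear this reading out as far as values can. A score is used only to describe, rank or filter peaks within this list. A lowest score of 30 means a permissive p-value limit of 1e-03, under which weak and chance regions enter the list. The running numbers go from 1 to 83676 without a break, and the peaks do not overlap.

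Groups were taken from the sample labels. That the list sets the ChIP library against the input was inferred, because the series has 1 library of each. As there was 1 library per group, nothing was tested between groups and no replicate error exists. Widths, scores and positions were summarised over peaks. Peaks per Mb used the distance between the first and last peak of each chromosome, because no mm9 chromosome lengths were used here. Counts have exact Poisson intervals, shares have Wilson intervals, and medians have percentile intervals from 2000 bootstrap resamples of the peaks, all at 95%. These cover counting error only and treat peaks as independent. Over the autosomes, counts per 1 Mb window had a variance 2.32 to 16.5 times their mean, so the Poisson intervals are too narrow. Windows of 1 Mb were counted by peak midpoint, leaving out the incomplete windows at chromosome ends. Spacing was compared with 100 random placements without overlap of the same peak widths on the same chromosome. Placements used the whole distance between the first and last peak, since no list of mm9 assembly gaps was used here, and unplaceable sequence raises the apparent clustering. Relations over the 19 autosomes were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 3 relations. Coordinates are printed 1-based.

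The placement, window, permutation and bootstrap steps were tested on simulated data. For 4000 simulated peaks placed uniformly, the ratio of the observed to the random share within 10 kb was 0.998. For simulated peaks with regional density alone, the ratio under placement within windows was 1.00. That density was set per window, in the same 1 Mb windows, so changes of density inside a window were not simulated. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

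Promoter and gene body shares, motif shares and 18 gene lists were fixed before the data were examined, with a rule for the genes to be named. They need the sequence and gene annotation of mm9. The gene table at hand was for another assembly, GRCm38.p6, and positions were not carried between builds, so these parts were not run and no gene was named. In place of the genes nearest to the 10 highest-scoring peaks, their positions are given. The alternatives tried were a minimum score of 50 and the joining of peaks within 1 kb, both fixed before the data were examined. A minimum score of 100, random placement within 1 Mb windows and the leaving out of chromosome 1 were added after seeing the data, as were the relations over the autosomes with all their alternatives, a minimum score of 50 included.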

Results

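HLXB9, also called HB9 or MNX1, is a homeodomain transcription factor of pancreatic β-cells and motor neurons. Regions enriched with an antibody against phosphorylated HB9 were mapped on the genome of MIN6-4N cells, a mouse insulinoma line. The method was chromatin immunoprecipitation and sequencing (ChIP-seq). The cells had been transfected with an HLXB9 expression plasmid, and chromatin was taken 48 hours later. There was 1 ChIP library and 1 input library, the latter being chromatin sequenced without an antibody, and reads were 36 bp long. Neither a control antibody nor untransfected cells had a library, so the peaks are not shown to be specific to phospho-HLXB9. The question was where in the genome phospho-HLXB9 is found. The comparison was taken to be that of the ChIP library with the input, as held in the authors' deposited list of peaks. With 1 library on each side no value has a replicate error, and no test between conditions was possible. Intervals given for counts cover counting error only and are too narrow where peaks cluster. Numbers of sequenced tags are not known, so the depth behind a peak is unknown. All positions are mm9. Genes were not assigned to the peaks, because no mm9 annotation was used here.

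The deposited list held 83676 regions on the 19 autosomes, the X and the Y chromosome. They were taken as regions in which the ChIP library exceeded the input. Together they covered 63.7 Mb, or 2.47% of the 2576 Mb between the first and last peak of each chromosome. Peaks had a median width of 657 bp (interquartile range across peaks 498 to 888 bp). Most peaks were weak. Scores are the authors' own and read as 10 times the negative log10 of the caller's p-value. The lowest was 30, equal to a p-value of 1e-03, and the median was 39.2 (interquartile range 33.7 to 49.4). Peaks with a score from 30 to 40 made up 52.7% of the list. A score of at least 50, equal to a p-value of 1e-05, was reached by 20181 peaks (24.1%). A score of at least 100 was reached by 1386 peaks (1.66%), and one of at least 200 by 95 peaks (0.114%). Since no false discovery rate accompanies the peaks used here, the share of chance peaks at each score is not known.

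**Figure D1:**
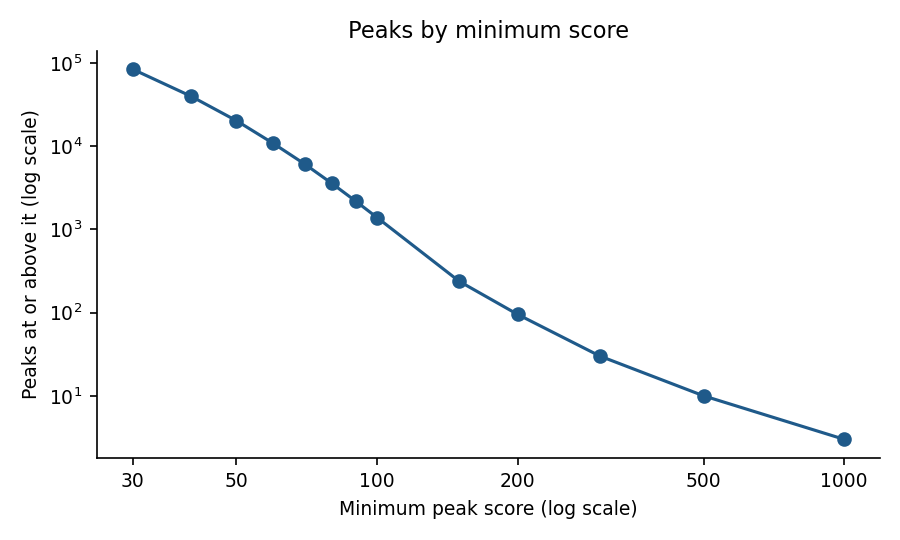
Number of peaks (y axis, log scale) at or above each minimum peak score (x axis, log scale); each point is 1 threshold. The count falls from 83676 at a score of 30 to 20181 at 50, 1386 at 100 and 95 at 200.

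The highest-scoring regions lay on several autosomes, and the first 3 stood far above the rest of the list. A score of at least 300 was reached by 30 peaks, and repeated sequence was not looked up in any of them. The highest score, 3100, belonged to a 6325 bp region on chromosome 17 (39979599 to 39985923). This round value may be the ceiling of the caller's scale, so only its rank is certain. The next was a 1734 bp region on chromosome 14 (103862620 to 103864353) with a score of 2123, and the third a 730 bp region on chromosome 4 (124546269 to 124546998) with a score of 1574. A 942 bp region on chromosome 5 (147072240 to 147073181) scored 711.8, and a 640 bp region on chromosome 3 (5860270 to 5860909) scored 608.6. The next 5 regions scored between 520.1 and 575.0. These were on chromosome 4 (34500713 to 34501417), chromosome 6 (87947361 to 87947797), chromosome 4 (55549701 to 55550639), chromosome 7 (85058422 to 85058946) and chromosome 2 (98506307 to 98507579). Among these 10 regions, the one on chromosome 7 had no other peak within 100 kb, whereas the third-ranked region on chromosome 4 had 20.

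Regions with a higher score were wider up to a score of 200. Median width was 588 bp (95% bootstrap interval 585 to 591) in the 44078 peaks with a score from 30 to 40. It was 672 bp (669 to 676) from 40 to 50, 797 bp (791 to 804) from 50 to 100 and 1232 bp (1197 to 1272) in the 1291 peaks from 100 to 200. In the 95 peaks with a score of 200 or more it was lower, at 861 bp (748 to 1052). Of these, 57.9% were narrower than 1 kb, against 33.2% of the peaks with a score from 100 to 200. Across all peaks, which are not independent replicates, the Spearman correlation of score and width was 0.34. The widest region of the list, 8978 bp on chromosome 1 (136091417 to 136100394), had a score of 78.3. All of the 10 widest regions lay on chromosomes 1, 7 and 17, with 3, 4 and 3 regions. On chromosome 7 they included regions of 6930 bp (52957643 to 52964572) and 6828 bp (19675728 to 19682555), with scores of 31.5 and 103.9.

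The autosomes differed in peak density, and the X chromosome carried few peaks. Peaks per Mb ranged over the autosomes from 22.8 on chromosome 18 (95% Poisson interval 21.8 to 23.8) to 45.5 on chromosome 11 (44.3 to 46.7). Chromosomes 19 and 17 followed chromosome 11, with 42.4 and 40.3 peaks per Mb. Chromosomes 2 and 14 were near the low end, with 24.9 and 26.9. On the X chromosome 281 peaks were spread over 163 Mb, which gave 1.73 peaks per Mb (1.53 to 1.94) against 34.6 over all autosomes. The X density was thus 5.00% of the autosomal one (4.43% to 5.62%), and the intervals of the X and of every autosome were apart. Of the X peaks, 18.1% had a score of at least 50 (Wilson 95% interval 14.1% to 23.1%), against 24.1% on the autosomes. Peaks of the X chromosome were also narrower, with a median of 437 bp against 658 bp on the autosomes. In 1 Mb windows with 1 to 10 peaks, peaks with a score from 30 to 40 had a median width of 421 bp on the X chromosome (95% bootstrap interval 408 to 438) and 438 bp on the autosomes (432 to 446). These intervals overlapped, though the X median lay below the autosomal interval. Density was matched only roughly, since X windows, empty ones included, held a median of 1 peak and a 90th percentile of 5. The 10th percentile of the autosomal windows was 14. The Y chromosome had 2 peaks, at 328005 to 328229 with a score of 102.5 and at 345864 to 346265 with a score of 36.5.

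**Figure D2:**
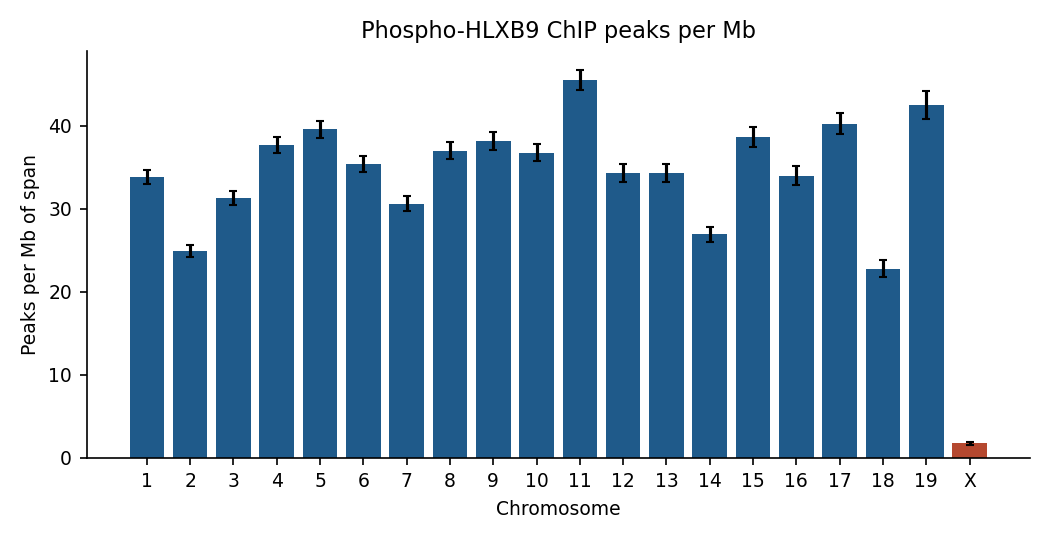
Peaks per Mb between the first and last peak of each chromosome (y axis), for 19 autosomes (blue) and the X chromosome (red); error bars are 95% Poisson intervals of the count. Autosomes range from 22.8 on chromosome 18 to 45.5 on chromosome 11, and the X chromosome has 1.73.

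Along the chromosomes, peaks were concentrated in some regions and sparse in others. The median autosomal window of 1 Mb held 34 peaks, with a 10th percentile of 14 and a 90th percentile of 56. The densest window, on chromosome 10 from 79000001 to 80000000, held 122 peaks, which covered 17.3% of it, and 62 of them had a score of at least 50. The adjoining window on chromosome 10 (80000001 to 81000000) held 91 peaks. Windows on chromosome 11 (102000001 to 103000000) and chromosome 8 (123000001 to 124000000) held 94 peaks each, and one on chromosome 5 (120000001 to 121000000) held 92. In all, 24 autosomal windows held at least 80 peaks, and chromosomes 4 and 11 had 4 of them each. Windows without a peak numbered 21 of 2387 on the autosomes (0.880%) and 54 of 162 on the X chromosome (33.3%). The longest autosomal stretch without a peak was 7.06 Mb on chromosome 7 (39326010 to 46383827), followed by 5.35 Mb on chromosome 14 (3209120 to 8555108). Assembly gaps and unmappable sequence were not excluded from these stretches. The windows and stretches named here are those with the highest counts and lengths, and the choice to name them was made after the values were seen.

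Chromosomes 1 and 2 were the extremes of evenness. On chromosome 1 the 10th and 90th percentiles of the windows were 24 and 44 peaks, and the variance of the counts was 2.32 times their mean, the lowest of the autosomes. On chromosome 2 the percentiles were 5 and 58.4 peaks and the variance was 16.5 times the mean, the highest of the autosomes. The densest window of chromosome 2 (32000001 to 33000000) held 90 peaks. Chromosome 1 also had the widest peaks, with a median of 756 bp, and 4.47% of its peaks were at least 2 kb wide. On chromosome 2 the median was 551 bp and this share was 0.0674%. On chromosome 18, none of the 1997 peaks was that wide. Chromosome 7 had the highest share of peaks at least 2 kb wide, 4.82%.

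**Figure D3:**
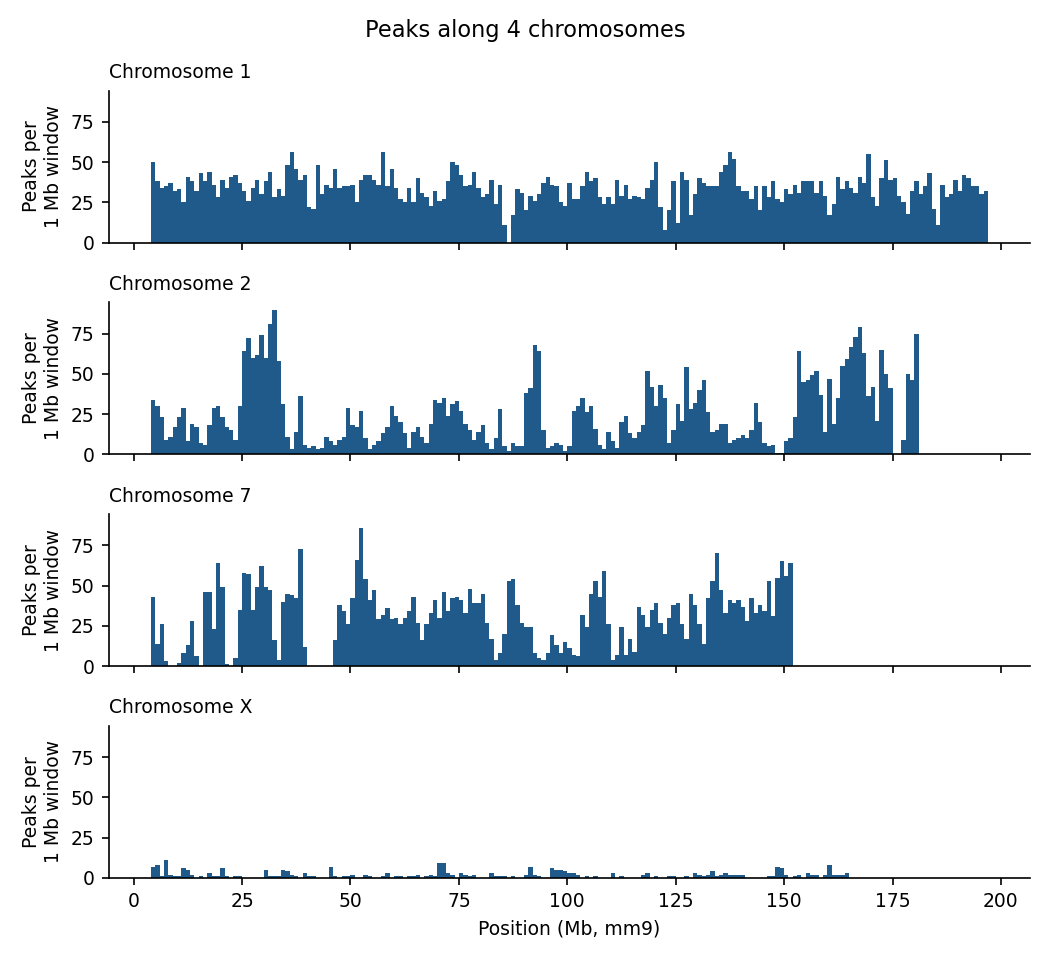
Number of peaks in each 1 Mb window (y axis) along chromosomes 1, 2, 7 and X (x axis, mm9 position in Mb); each bar is 1 window. Counts vary less along chromosome 1 (10th to 90th percentile 24 to 44) than along chromosome 2 (5 to 58.4). They are interrupted by a 7.06 Mb stretch without peaks on chromosome 7, and are low on the X chromosome (0 to 5).

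Across the 19 autosomes, chromosomes with more peaks per Mb had wider and somewhat higher-scoring peaks. Peaks per Mb and median width had a Pearson r of 0.79 (permutation p = 9e-05, adjusted p = 0.00027 over the 3 relations computed) and a Spearman rho of 0.72 (permutation p = 0.00078, adjusted 0.0023). Without chromosomes 2 and 18, the farthest from the median density, r was 0.60 (permutation p = 0.01). Chromosome 1 lay off this relation, and without it r was 0.92, a rise that follows from this choice. Peaks per Mb and the share of peaks with a score of at least 50 had r = 0.66 (permutation p = 0.002, adjusted 0.0023) and rho = 0.64 (permutation p = 0.0037, adjusted 0.0056), and r = 0.55 without the same chromosomes (permutation p = 0.024). For the median score r was 0.66 (permutation p = 0.0023, adjusted 0.0023) and rho 0.59 (permutation p = 0.0095, adjusted 0.0095). Without chromosomes 2 and 18, r fell to 0.42 (permutation p = 0.093), so that it passed the threshold of 0.05 only with these chromosomes included. Permutation tests were two-sided, and all values come from the same pair of libraries. Number, width and score of the peaks also come from the same calling at the same limit. Calling alone might therefore link them, and the p-values do not address this.

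**Figure D4:**
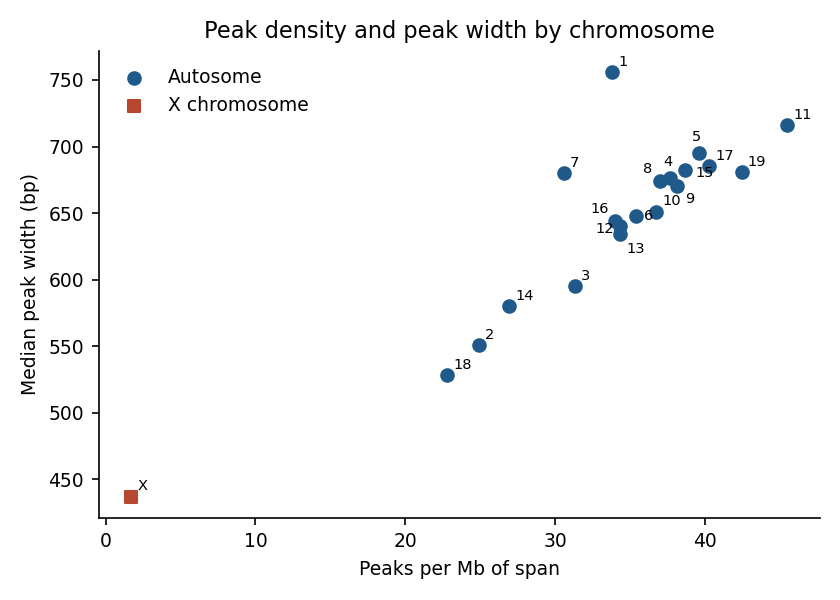
Median peak width in bp (y axis) against peaks per Mb (x axis) for each chromosome, labelled by its name; blue circles are autosomes and the red square is the X chromosome. Width rises with density over the autosomes (r = 0.79); chromosome 1 lies above the others at 756 bp, and the X chromosome lies at 1.73 peaks per Mb and 437 bp.

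Neighbouring peaks lay closer together than randomly placed ones. The next peak was within 10 kb for 36.3% of peaks, against 30.3% ± 0.134 (SD over 100 random placements of the same widths along each chromosome). It was within 1 kb for 5.71% of peaks, against 3.56% ± 0.0709. Both observed shares lay above all 100 placements. Part of this came from the uneven density along chromosomes. When peaks were placed at random within their own 1 Mb windows, 34.3% were followed within 10 kb and 4.25% within 1 kb. Both observed shares again lay above all placements. Changes of density inside a window are not accounted for by this placement. Joining peaks up to 1 kb apart left 78901 regions, of which 4102 held 2 peaks and 320 held at least 3. The region with the most peaks held 6 over 6.22 kb of chromosome 11 (96128618 to 96134834), with a highest score of 76.7.

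**Figure D5:**
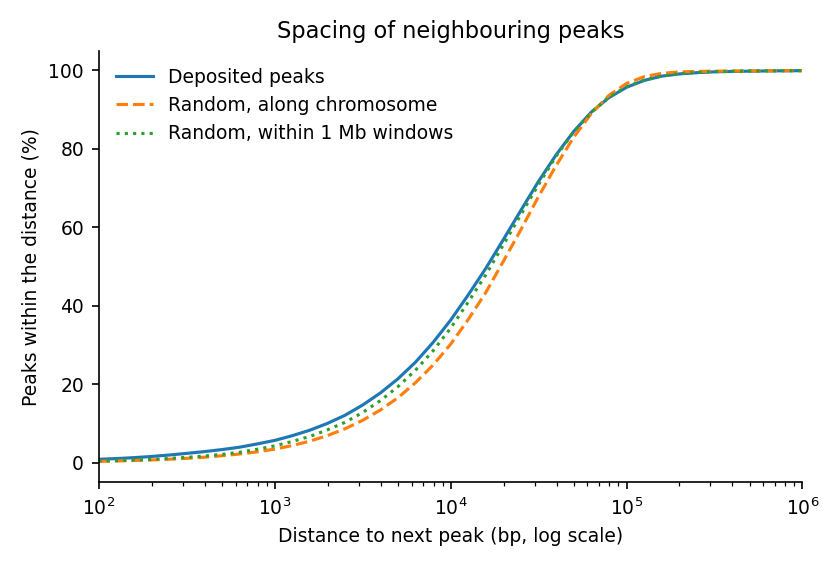
Share of peaks whose next peak lies within a given distance (y axis, %) against that distance in bp (x axis, log scale); the solid line is the deposited peaks, the dashed line 1 random placement along each chromosome and the dotted line 1 random placement within 1 Mb windows. At 10 kb the deposited peaks stand at 36.3%, above the means of 30.3% and 34.3% over 100 placements of each kind.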

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

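The number of peaks depends on the score limit. It was 83676 in the whole list, 20181 at a minimum score of 50 and 1386 at a minimum of 100, a limit chosen after seeing the data. Joining peaks within 1 kb left 78901. The density of the X chromosome was 5.00% of the autosomal one in the whole list and 3.76% (95% Poisson interval 2.80% to 4.94%, 51 X peaks) at a minimum score of 50. At a minimum of 100 it was 6.46% (2.37% to 14.1%), which rests on 6 X peaks. The ratio of peaks per Mb on chromosome 11 to chromosome 18 was 2.35 at a minimum score of 50, against 45.5 over 22.8 peaks per Mb in the whole list. The observed share of neighbours within 10 kb was 1.20 times the random one in the whole list, 1.52 times at a minimum score of 50 and 1.06 times with placement within 1 Mb windows. Within 1 kb these ratios were 1.60, 2.19 and 1.34. In each of these settings the observed share lay above all 100 placements. The correlation of peaks per Mb and median width over the autosomes was 0.79 in the whole list. It was 0.81 at a minimum score of 50 (permutation p = 4e-05) and 0.92 without chromosome 1 (permutation p = 1e-05, the smallest the permutations can give). Chromosome 1 was left out after it was seen to lie off this relation, so the rise to 0.92 follows from that choice. Alternatives planned for promoter, gene body, gene list and motif results were not run, since those results need mm9 sequence or annotation. No library could be left out, because there is 1 per group. The unknown tag numbers limit every statement about weak peaks: a region without a peak is one where the caller's limit was not passed, not one shown to be unbound.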

Other observations

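The tests on the X chromosome and on chromosome 1 were chosen or changed after the results were seen. The test on neighbours of the highest-scoring peaks was set out before its values were seen. No biological explanation was tested, because the design has no second condition. Each explanation is a hypothesis from 1 pair of libraries.

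Peak width changed along some chromosomes. On chromosome 7 the position that best divided peaks with a score from 30 to 40 by width was 58 Mb, with a median width of 795 bp before it and 532 bp after it. Of all peaks before this position 12.5% were at least 2 kb wide, against 0.769% after it. On chromosome 4 the widths rose from 556 bp to 824 bp at 128 Mb, and on chromosome 15 from 538 bp to 734 bp at 72 Mb. On chromosome 1 the median width was 682 bp before and 865 bp after 177 Mb. This was the last position searched there, so it need not mark where the widths changed. Chromosome 18 had the smallest step, a ratio of 1.05. Each position was placed where the widths differed most among the positions searched, which left out those near the chromosome ends. These differences therefore describe the peaks and test nothing. Runs of close peaks were found on chromosome 7 (12595596 to 12601360), chromosome 9 (30749953 to 30754809) and chromosome 15 (101627578 to 101635016), each with 5 peaks. A run of 4 peaks on chromosome 2 (98502107 to 98507579) included the region with a score of 520.1 that was among the 10 highest.

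The X chromosome had 5.00% of the autosomal peak density. Removal of X peaks from the list after calling is argued against by the running peak numbers, which have 0 breaks on the X chromosome. A lower density of tags on the X chromosome, as a lower copy number might give, would lower its peak number if the caller measured peaks against a background set over the whole genome, which the sources used here do not state. Peak widths do not decide this: in windows with 1 to 10 peaks, the X median of 421 bp (95% bootstrap interval 408 to 438) overlapped the autosomal 438 bp (432 to 446). Overlap of the intervals is not a test of the difference, which was not tested. Within the range of 1 to 10, the numbers of peaks per window were not matched further. Lower tag density and a thinner set of sites therefore cannot be told apart, because tag numbers were not analysed here.

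Chromosome 1 had wide and evenly spread peaks. Its median width lay 120 bp above the line of width on density through the other autosomes, where the largest residual was 69.0 bp on chromosome 7. Chromosome 1 was picked for its width after the values were seen and was left out of the line. The residual therefore describes its distance and tests nothing. In windows with 25 to 45 peaks, peaks with a score from 30 to 40 had a median width of 682 bp on chromosome 1 (669 to 695), against at most 588 bp on the other autosomes taken whole. The wider parts of chromosomes 7, 4 and 15 named above, which were not matched by peak number, had medians of 795 bp, 824 bp and 734 bp. A higher tag density on chromosome 1, possibly from extra copies, might widen peaks under the same assumption of a background set over the whole genome. The peak number was 33.8 per Mb (95% Poisson interval 33.0 to 34.6), not above the 34.6 over all autosomes. This interval is too narrow, since window counts on chromosome 1 had a variance 2.32 times their mean. Joining of neighbouring peaks would also lower the number, so a higher tag density and wider bound regions both stay open.

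The 95 peaks with a score of 200 or more were narrower than those from 100 to 200. They had a median of 7 other peaks within 100 kb (95% bootstrap interval 6 to 8), against 9 for scores from 100 to 200 and 8 for scores from 30 to 40. No other peak lay within 100 kb of 4 of the 95, or 4.21% (Wilson 95% interval 1.65% to 10.3%), against 0.697% (0.367% to 1.32%) of the peaks from 100 to 200. Within this set, the 55 peaks narrower than 1 kb had a median of 6 other peaks nearby and the 40 wider ones 8.5. For short repeated sequence collapsed in the reference, the prediction set out was no more neighbours than peaks with a score from 30 to 40 have. This was met, with the upper end of the interval at their value. The number of neighbours cannot decide whether repeats are a source, because a repeat may lie in a sparse or a dense region. Repeats were not looked up, and strong binding sites outside regions dense in peaks would give the same values.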
